A study of Mus musculus with 6 samples.

How the data were processed

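Bulk RNA sequencing was done on dendritic cells (DC) sorted from pooled mouse tumors, with 6 libraries in 3 groups of 2. Per the labels' protocols, libraries were made with a stranded low-input total RNA kit that removes ribosomal cDNA, and were sequenced on a NextSeq instrument. The labels' molecule field instead names polyA RNA, and these statements were not reconciled. The deposited table holds RSEM estimated counts per gene symbol, not normalized, with 1 column per library; 16.1% of its values are not whole numbers. Per the submitters' processing notes, the tools were Bowtie 1.2.3 and RSEM 1.3.1 and the genome build was mm9. The gene annotation, the strand setting and any read filter are not given in the sources used here. RSEM shares reads that fit several genes between them by a model, so values of single members of near-identical families (histone, Oas, Ifit, Gbp, Sirpb, Pir and classical MHC genes) are uncertain. Without a stated strand setting, overlapping and antisense genes cannot be separated either. The reference annotation used for other purposes belongs to another build, so no coordinates are given.

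The table lists 23224 gene symbols, none of them blank or a total, and every value column was matched to 1 library by its label. In the symbol column 25 genes appear as calendar dates, and 3-Sep stands for the gene Sept3. Total estimated counts ran from 6023510 to 15368616 per library. A count of 3, used as the limit for genes at 0, corresponds to 0.144 CPM over the CD103+ DC1 group, 0.101 CPM over the Rag2-/- ISG+ DC group and 0.142 CPM over the WT ISG+ DC group. These limits cover counting error alone, because reads without molecular identifiers are not independent molecules. An at-least fold sets the mean CPM of the other group against this limit, so single libraries can lie under that fold.

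Estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given, which left 13223 genes, and libraries were scaled by TMM factors. One quasi-likelihood fit (glmQLFit, glmQLFTest) over all 6 libraries gave both comparisons, so the 3 groups share one estimate of the spread. Residual degrees of freedom were 3 per gene, the prior added 7.34, and the common biological coefficient of variation was 0.703. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken from the F statistic. CPM values are depth-normalized counts, scaled by the TMM factors, and given as mean ± SD over the 2 libraries of a group.

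Gene lists, 21 in number, were written before the data were examined. They covered DC1 and CD11b+ DC identity, type I interferon-stimulated and interferon-gamma-associated genes, MHC class I and class II presentation and the mature regulatory DC program. They also covered cytokines, chemokines and costimulation, phagocytic, Fc and pattern receptors, nucleic acid and microbial sensing, proliferation, and immediate-early and heat-shock genes. Markers of macrophages and monocytes, T cells, B cells, NK cells, neutrophils, plasmacytoid DC, fibroblasts and fibrosarcoma matrix, erythroid cells and sex-linked genes completed them. Of the 507 entries, 501 were found in the table, some under an older symbol. The 19 lists with at least 5 tested members other than the erythroid and sex-linked lists were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over those lists. Camera was run again with the correlation estimated per list. The estimate lay under the preset 0.01 in some lists whose adjusted p still rose in that run. Between populations it was -0.029 for CD11b+ cDC2 identity and 0.0046 for interferon-gamma-associated genes. A call lost in that run therefore does not by itself show that the genes of a list were correlated. As a further alternative fry was run, which tests a list against no change, whereas camera tests it against the other genes.

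Genes were named by a rule also set before the data were examined. It took the 6 genes with the greatest rise and the 6 with the greatest fall among those that passed with a mean of at least 10 CPM, non-overlapping groups and no predicted gene name. It also took up to 3 members of each list with the smallest p, and a fixed set of lineage, interferon and recombinase genes. Any gene outside the rule is stated to have been chosen after its values were seen.

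The procedure was tested on simulated counts, drawn from each gene's mean over all 6 libraries and from the real library sizes. Only genes with a mean of at least 10 CPM were changed, so recovery of lower genes was not measured. For the comparison of populations the procedure recovered 1.6%, 38.8%, 75.2% and 84% of genes changed by 2-fold, 4-fold, 8-fold and 16-fold. There 12651 genes were tested, and 4.95% of the calls were false. For the comparison of hosts the shares were 4.8%, 40%, 76.4% and 89.6% over 12642 genes, with 5.72% of calls false. Changes of 2-fold were therefore rarely detectable with 2 libraries per group.

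The alternatives tried were DESeq2 1.42.0, limma-voom with sample weights, median-ratio and upper-quartile scaling, no low-count filter, and a filter of 5 CPM in 2 libraries. Further alternatives were a fit of the 4 libraries compared, a threshold of 0.1, a test against 1.5-fold, a replicate block, pooled ISG+ DC of both hosts, and each replicate left out. Removing Rn45s, Rpph1, Malat1 and Lars2, and leaving CD103+ DC1 replicate 3 out of the comparison of hosts, were chosen after seeing the data. Figures were drawn with matplotlib.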

Results

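Tumor DC were profiled by bulk RNA sequencing 7 days after MC57-SIY cells had been implanted under the skin of C57BL/6 mice. MC57 is a mouse fibrosarcoma line, and SIY is a model peptide antigen seen by CD8+ T cells. The 3 groups, with 2 libraries each, were CD103+ DC1 and ISG+ DC from hosts labelled Rag2-/- and ISG+ DC from hosts labelled WT. CD103+ DC1 are the conventional DC known for cross-presentation. The labels name ISG+ DC without giving the sort gate, and ISG usually stands for interferon-stimulated gene. Rag2 is needed for antigen receptor recombination, so Rag2-/- mice lack mature T and B cells. The labels state that tumors were pooled and that each sample type came from 2 independent experiments. The p-values of single genes rest on the spread between libraries, shared over the 3 groups and moderated by the prior. Camera p-values with the preset correlation set the genes of a list against the other genes. They do not measure the spread between libraries.

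Total estimated counts were 14378365 and 6023510 in CD103+ DC1 (replicates 2 and 3), 15368616 and 13545968 in Rag2-/- ISG+ DC (replicates 2 and 3), and 11440669 and 10455861 in WT ISG+ DC (replicates 1 and 2). Between 12323 and 14051 genes had a count in each library. CD103+ DC1 replicate 3 stood apart from the rest. It had the lowest total, and Rpph1, the RNA of ribonuclease P, took 1.11% of its counts against 0.303% to 0.383% in the others. Its Spearman correlation over genes with the other 5 libraries was 0.858 to 0.902, against 0.94 and 0.93 within the Rag2-/- and WT ISG+ DC groups. CD103+ DC1 replicate 2 correlated better with Rag2-/- ISG+ DC replicates 2 and 3 (0.936 and 0.918) and WT ISG+ DC replicate 1 (0.908) than with its own replicate (0.902). Replicates of each group differed far beyond counting noise, with a chi-square per degree of freedom of 93 in CD103+ DC1, 47.6 in Rag2-/- ISG+ DC and 41.1 in WT ISG+ DC. The first 2 principal components held 40.2% and 20.7% of the variance.

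Rag2, the gene that distinguishes the hosts, was found at low counts in the libraries labelled Rag2-/- alone. It had 39 and 11 estimated counts in CD103+ DC1 and 40 and 2 in ISG+ DC labelled Rag2-/-, against 0 and 0 in ISG+ DC labelled WT. Between the ISG+ DC groups this low-count difference did not pass (edgeR adjusted p = 0.588). Rag1 was at 0 in all 6 libraries. The 0 counts of Rag2 in the group labelled WT would speak against that label only if DC express Rag2, which these data do not show. Which part of Rag2 the allele lacks is not given in the sources used here, so reads outside that part would not check the labels. The host names below are therefore those of the labels, and every direction between hosts rests on them.

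The first comparison asked how ISG+ DC differ from CD103+ DC1 within hosts labelled Rag2-/-. ISG+ DC had lower levels of DC1 identity genes and higher levels of CD11b+ cDC2 genes as groups. Macrophage and phagocytic receptor genes were higher as groups by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.0566 and 0.0556). By fry both lists were higher (adjusted p = 0.0123 and 0.00776), though 3 of the 38 receptors fell. ISG+ DC also had higher levels of part of the type I interferon-stimulated genes, such as Ifit1 (4.82-fold) and Oasl2 (4.89-fold). Of 13223 genes tested, 488 differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 374 higher and 114 lower in ISG+ DC. At an unadjusted p under 0.05 there were 1972 genes. All 488 had non-overlapping groups, which chance gives to 33.3% of genes with 2 libraries against 2. The count was 2068 without CD103+ DC1 replicate 2, 774 without CD103+ DC1 replicate 3 and 278 without Rag2-/- ISG+ DC replicate 3.

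Of 19 DC1 identity genes tested, 13 fell and none rose in ISG+ DC, and 15 fell when adjusted over the list alone. The median log2 fold change was -2.93 (camera adjusted p = 1.59e-36, and adjusted p = 0.046 with an estimated correlation). Xcr1, the receptor for XCL1, was at 6.81 ± 3.2 CPM against 273 ± 60.1 in CD103+ DC1, a log2 change of -5.33 ± 0.47 (SE). Clec9a, a receptor for dead cells, changed by -5.10 ± 0.53 and Itgae, which encodes CD103, by -6.61 ± 0.89. Irf8, a transcription factor of the DC1 lineage, fell by 2.93 ± 0.38 on the log2 scale. Sept3 fell 23.2-fold and Ppt1 6.39-fold. With 1 library left out, Itgae ran from -9.05 (without ISG+ DC replicate 3) to -5.73 (without ISG+ DC replicate 2), and Clec9a reached -5.80 without ISG+ DC replicate 2. Without CD103+ DC1 replicate 2, Irf8 was at -2.21 and Sept3 at -3.91. Batf3, another DC1 factor, was at 9.58 ± 0.995 CPM against 24.4 ± 10.1 and did not pass (edgeR adjusted p = 0.382).

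The CD11b+ cDC2 list went the other way, with 12 of 22 genes higher, none lower and 15 higher when adjusted over the list alone. Its median log2 fold change was 3.34 (camera adjusted p = 1.37e-30, and adjusted p = 0.0193 with an estimated correlation). Itgam, which encodes CD11b, was at 1263 ± 159 CPM in ISG+ DC and 79.2 ± 7.88 in CD103+ DC1, a 15.9-fold rise (edgeR adjusted p = 8.88e-05). S100a4 rose 24-fold and Clec10a 10.2-fold. Sirpa (673 ± 24.7 against 24.5 ± 24.9 CPM) rose by 4.75 on the log2 scale, or 6.61 without CD103+ DC1 replicate 2 and 4.02 without replicate 3. Irf4, a cDC2 transcription factor, rose by 3.33, or 3.95 without CD103+ DC1 replicate 3.

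Macrophage and monocyte markers moved with the population as well. Of 30 tested, 18 rose and none fell, and 21 rose when adjusted over the list alone (median 2.28, camera adjusted p = 4.41e-31, and adjusted p = 0.0566 with an estimated correlation). Over all genes, 21 rose and 1 fell without CD103+ DC1 replicate 2. Csf1r, the receptor for M-CSF, rose 14.3-fold, Fcgr1, the high-affinity IgG receptor CD64, 10.8-fold and the chemokine receptor Ccr2 6.14-fold. Among phagocytic, Fc and pattern receptors, 19 of 38 rose and 3 fell, with 27 and 4 when adjusted over the list alone (median 1.96, camera adjusted p = 5.70e-26, and adjusted p = 0.0556 with an estimated correlation). Clec4a1 rose 41.9-fold in that list, and 18 rose and 1 fell without ISG+ DC replicate 3.

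**Figure D1:**
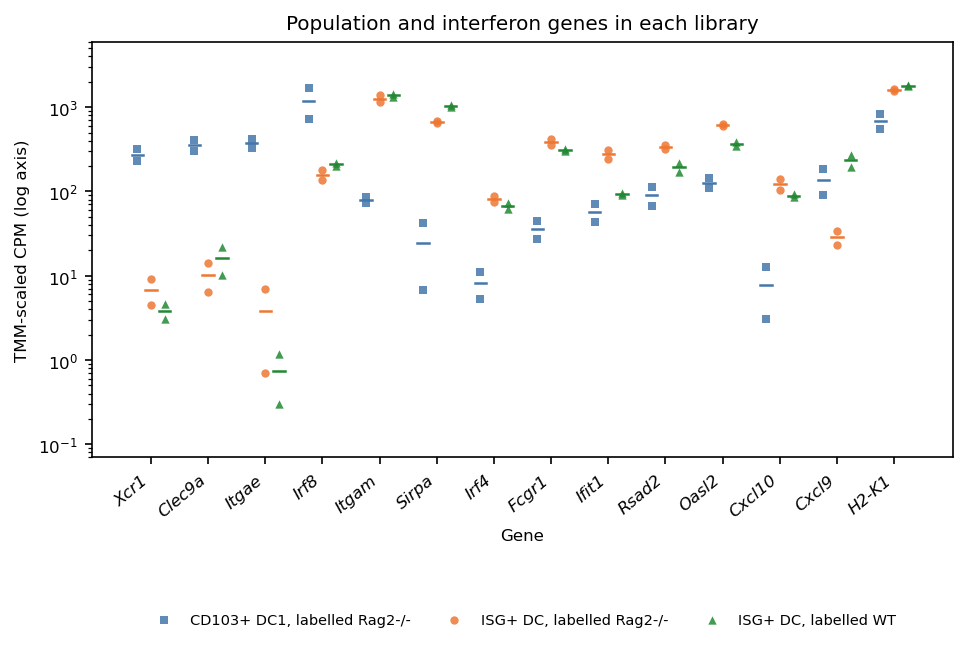
TMM-scaled CPM on a log axis of 14 lineage and interferon genes in each of the 6 libraries, with points for libraries, short bars for group means, and colors and shapes for the 3 groups. The 2 ISG+ DC groups lie near each other for Itgam, with 1263 CPM on average in the group labelled Rag2-/- against 79.2 in CD103+ DC1, and all 4 ISG+ DC libraries lie below CD103+ DC1 for Xcr1, Clec9a and Itgae.

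Type I interferon-stimulated genes rose in part. Of 45 tested, 15 rose, none fell and 30 did not pass, and 21 rose when adjusted over the list alone. With 1 library left out 11 to 24 rose, and 1 fell without CD103+ DC1 replicate 2. Their median log2 fold change was 0.78 (camera adjusted p = 4.81e-17, and adjusted p = 0.0556 with an estimated correlation). Ifit1, an inhibitor of viral translation, was at 275 ± 48.9 CPM against 56.9 ± 18.6, and Rsad2, the antiviral enzyme viperin, at 338 ± 25.4 against 90.1 ± 32.5. Siglec1, a sialic acid receptor of macrophages, rose 8.33-fold and Ms4a4c 8.16-fold. Isg15 (157 ± 2.66 against 128 ± 32.6 CPM, edgeR adjusted p = 0.756) and Mx1 (626 ± 45.3 against 481 ± 73.2 CPM, edgeR adjusted p = 0.53) did not pass. The sensing list, with 7 of 38 genes higher and 1 lower (15 and 2 when adjusted over the list alone), had a median of 0.71 (camera adjusted p = 3.25e-07, and adjusted p = 0.0612 with an estimated correlation). Over all genes, 15 rose and 2 fell without CD103+ DC1 replicate 2, 4 rose and 2 fell without ISG+ DC replicate 2, and 4 rose and 1 fell without ISG+ DC replicate 3. Its Ddx58, the RNA sensor RIG-I, rose 6.44-fold, Tlr2 14.1-fold and Tlr8 30.3-fold; Tlr8, at a log2 change of 4.92, was at 4.17 without CD103+ DC1 replicate 2 and 5.84 without replicate 3.

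Among 27 interferon-gamma-associated genes, Gbp2 (4.88-fold) and Gbp7 (3.95-fold) rose and Cxcl9 fell, and when adjusted over the list alone 7 rose and 2 fell. Over all genes, 10 rose and 2 fell without CD103+ DC1 replicate 2, 7 and 1 without CD103+ DC1 replicate 3, and 4 and 0 without ISG+ DC replicate 2. The list's median was 0.75 (camera adjusted p = 0.00028, and adjusted p = 0.0612 with an estimated correlation). Cxcl9 and Cxcl10, both ligands of CXCR3, moved in opposite directions. Cxcl9 fell by 2.25 ± 0.40 on the log2 scale, from 137 ± 66.9 to 28.8 ± 7.84 CPM, whereas Cxcl10 rose by 3.91 ± 0.58, from 7.83 ± 6.71 to 122 ± 24.1 CPM. The fall of Cxcl9 lost its call without Rag2-/- ISG+ DC replicate 2, at -1.99, and with the ISG+ DC of both hosts pooled, at -0.74. Without CD103+ DC1 replicate 3, Cxcl9 was at -1.62 and Cxcl10 at 3.30, and without CD103+ DC1 replicate 2 Cxcl10 was at 5.29. In the list of cytokines, chemokines and costimulation, 7 of 32 rose and 1 fell, with 12 and 3 when adjusted over the list alone (median 1.21, camera adjusted p = 6.73e-06, and adjusted p = 0.0566 with an estimated correlation). Over all genes, 11 rose and 2 fell without CD103+ DC1 replicate 2, 10 and 3 without CD103+ DC1 replicate 3, and 4 and 1 without ISG+ DC replicate 3. The chemokine Ccl9 rose 11.4-fold, and Cxcl2, at 0 in CD103+ DC1, was at least 69.5-fold higher. The fitted log2 change of Cxcl2 over that 0, 9.90 or 8.91 without ISG+ DC replicate 3, is not a measured size.

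MHC class I presentation genes did not move as a group (median 0.08, camera adjusted p = 0.892), with 3 of 23 higher and 2 lower, and 4 and 4 when adjusted over the list alone. H2-K1, a classical class I heavy chain, rose 2.3-fold to 1594 ± 69.6 CPM, whereas Psmb9, an immunoproteasome subunit, fell by 1.79 and Psme1, a proteasome activator, by 1.29 on the log2 scale. B2m was at 1204 ± 103 against 789 ± 135 CPM (edgeR adjusted p = 0.207). Without Rag2-/- ISG+ DC replicate 2 and without replicate 3, H2-K1 (1.16 and 1.25), Psmb9 (-1.79 in both) and Psme1 (-1.25 and -1.32) kept their direction and lost their calls, and no class I gene passed; 6 rose and 5 fell without CD103+ DC1 replicate 2. In class II presentation 3 of 15 rose and none fell, with 6 higher when adjusted over the list alone (median 0.68, camera adjusted p = 2.44e-05, and adjusted p = 0.199 with an estimated correlation). These were the lysosomal enzymes Ctss (4.02-fold), Lgmn (3.23-fold) and Ifi30 (3.2-fold); 9 rose without CD103+ DC1 replicate 2.

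Proliferation genes were lower in ISG+ DC, with 2 of 30 passing and 8 when adjusted over the list alone, all lower (median -1.24, camera adjusted p = 2.60e-09, and adjusted p = 0.0612 with an estimated correlation). Over all genes, 10 fell without CD103+ DC1 replicate 2, 1 without either ISG+ DC replicate and 23 with the ISG+ DC of both hosts. Mki67 fell by 1.84 and Top2a by 1.39 on the log2 scale; Top2a lost its call without Rag2-/- ISG+ DC replicate 2, at -1.53, and without replicate 3, at -1.26. Of 22 immediate-early and heat-shock genes, whose levels can follow tissue dissociation, 6 rose and none fell, with 7 higher when adjusted over the list alone (median 0.34, camera adjusted p = 0.00604, and adjusted p = 0.29 with an estimated correlation). Jun rose 4.06-fold, Dusp1 2.73-fold and Hspa1b 2.6-fold. Dusp1 lost its call without ISG+ DC replicate 3, at 1.26, and Hspa1b without replicate 2, at 1.04. Over all genes, 7 rose and 1 fell without CD103+ DC1 replicate 2, and 3 and 2 rose without ISG+ DC replicates 2 and 3. The list's call was lost without replicate 3, at a median of 0.06, and the list did not pass fry (adjusted p = 0.0533).

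In the mature regulatory DC list, Spred1 (3.29-fold) was the 1 gene of 29 that passed, without a call for the list (camera adjusted p = 0.809). When adjusted over the list alone 1 rose and 1 fell. Spred1 lost its call without ISG+ DC replicate 3, at 1.38, where no gene of the list passed; 7 rose without CD103+ DC1 replicate 2, and 1 rose and 4 fell without CD103+ DC1 replicate 3. Il12b was at 29.6 ± 11 against 119 ± 71.9 CPM (edgeR adjusted p = 0.0638), and Ccr7, the receptor for lymph node homing, at 87.2 ± 4.18 against 137 ± 89.4 (edgeR adjusted p = 0.56).

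T cell (13 tested), B cell (7) and NK cell (7) lists had no call by camera (adjusted p = 0.892, 0.907 and 0.368). Fcrla, on the B cell list, was at 22.8 ± 10.2 CPM in CD103+ DC1 and 0 in ISG+ DC, at least 225-fold lower. It was the 1 member of the 3 lists to pass over all genes, while 2 T cell markers were higher when adjusted over that list alone. Without CD103+ DC1 replicate 2, 1 T cell marker rose and 1 fell, and without replicate 3, 1 rose; 1 NK cell marker rose in each of these fits. On the neutrophil list Il1r2 (14.4-fold) and Trem1 (30.8-fold) rose among 7 tested, 3 when adjusted over the list alone. Both genes are also expressed by monocytes and macrophages. Trem1, at a log2 change of 4.94, was at 3.85 without CD103+ DC1 replicate 2 and 7.50 without replicate 3. That list's median was 1.49, or 1.10 with a gene at 0 set at its limit (camera adjusted p = 0.0002, and adjusted p = 0.0732 with an estimated correlation), and the call was lost without CD103+ DC1 replicate 2, at 2.08, and without ISG+ DC replicate 2, at 0. On the plasmacytoid DC list Cybb (23.4-fold), the phagocyte oxidase, and Lair1 (6.55-fold) rose among 10 tested, 4 when adjusted over the list alone (median 0.68, camera adjusted p = 7.63e-05, and adjusted p = 0.0732 with an estimated correlation). Fn1 (5.35-fold) was the 1 of 24 fibroblast and matrix genes to pass, over all genes and over the list alone, and the list had no call (camera adjusted p = 0.321). Without CD103+ DC1 replicate 2, 3 neutrophil, 5 plasmacytoid DC and 3 fibroblast genes rose. Of the 13 lists called, those for DC1 and CD11b+ cDC2 identity held with an estimated correlation.

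The greatest rises by fold were in genes at 0 in CD103+ DC1 after rounding. Relative to a limit of 3 counts over the group, Sirpb1b was at least 411-fold higher, F11r 243-fold, Pira1 198-fold, Sh2d1b1 170-fold, Emr4 167-fold and Cyp4f18 145-fold. The greatest falls other than Fcrla and Itgae were in Gcet2 (-6.74), Cxcr3 (-5.91), Cadm1 (-5.80) and Sema4f (-5.76). Cxcr3 lost its call without ISG+ DC replicate 2, at -5.63, and without replicate 3, at -6.25. These sizes depended on single libraries: Pira1 had 47.4 and 9.39 CPM in the 2 ISG+ DC libraries. Its fitted log2 change was 11.41, or 9.72 without replicate 2 and 12.10 without replicate 3. With CD103+ DC1 at 0 these fitted values are not measured sizes. The limit above sets the mean of both ISG+ DC libraries against 3 counts, so it does not bound each library. Without ISG+ DC replicate 2 and without replicate 3, Cadm1 was at -7.28 and -5.10, and Sema4f at -7.41 and -5.03. Gcet2 was at -5.76 without replicate 3. Without replicate 2 the ISG+ DC library left had 0 counts of Gcet2, so its fitted -14.07 is not a measured size. The same holds for genes with a group at 0: F11r at 11.04 without replicate 2, Sh2d1b1 at 10.60 without replicate 3, and Fcrla at -10.47 without CD103+ DC1 replicate 2.

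The second comparison asked how ISG+ DC from hosts labelled WT differ from those of hosts labelled Rag2-/-, which lack mature T and B cells if the labels hold. In the group labelled WT, Arg1 and Nos2, which encode the arginine-consuming enzymes arginase 1 and inducible nitric oxide synthase, rose 34.3-fold and 184-fold. Nos2 had 14 and 41 counts in the libraries labelled Rag2-/-, and its log2 change of 7.52 ran from 6.86 (without WT replicate 2) to 8.63 (without Rag2-/- replicate 3). Interferon-gamma-associated genes were higher as a group. Macrophage genes were so by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.06). By fry they were higher (adjusted p = 0.0253). Type I interferon-stimulated genes and proliferation genes were lower as groups, with Ifit3 falling 5.24-fold and Mki67 2.92-fold. Of 13223 genes tested, 73 differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 38 higher and 35 lower. At an unadjusted p under 0.05 there were 1307. The count depended on single libraries, at 27 without Rag2-/- ISG+ DC replicate 2, 198 without WT ISG+ DC replicate 1 and 801 without CD103+ DC1 replicate 3, which enters through the shared spread and the choice of genes tested (14270 without it). All 73 were among the 801.

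Type I interferon-stimulated genes were lower in 44 of 45 members by sign. Over all genes tested 5 fell and none rose, and 27 fell when adjusted over the list alone. The median log2 fold change was -0.93 (camera adjusted p = 5.44e-24, and adjusted p = 0.0495 with an estimated correlation). Mx1, an antiviral GTPase, was at 183 ± 27.3 CPM against 626 ± 45.3, a log2 change of -1.78 ± 0.25. Ifit3 was at 136 ± 6.08 against 713 ± 93.7 CPM and Phf11 at 28.9 ± 2.95 against 162 ± 11.5. Ifit1 (93.7 ± 3.44 against 275 ± 48.9 CPM, edgeR adjusted p = 0.0611) and Isg15 (82.2 ± 19.9 against 157 ± 2.66 CPM, edgeR adjusted p = 0.298) did not pass. Over all genes, 1 fell without Rag2-/- ISG+ DC replicate 2, 3 without any other library of the groups compared, and 26 without CD103+ DC1 replicate 3. Mx1 lost its call without Rag2-/- ISG+ DC replicate 2, at -1.70, and without WT replicate 2, at -1.64, and Ifit3 lost it without Rag2-/- replicate 2, at -2.25.

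Interferon-gamma-associated genes went the other way, with 6 of 27 higher, none lower and 10 higher when adjusted over the list alone. The count moved to 1 higher and 1 lower without Rag2-/- ISG+ DC replicate 2, to 3 higher without Rag2-/- replicate 3 or WT replicate 2, and to 12 higher and 1 lower without CD103+ DC1 replicate 3. Their median was 1.18 (camera adjusted p = 3.98e-18, and adjusted p = 0.0495 with an estimated correlation). Nos2 was at 353 ± 181 CPM against 1.94 ± 1.49. Cxcl9 was at 233 ± 55 against 28.8 ± 7.84 CPM and Gbp2 at 745 ± 182 against 215 ± 18.9. Cd274, which encodes the checkpoint ligand PD-L1, was at 513 ± 20.8 against 124 ± 8.96 CPM. Cxcl10 (89.3 ± 4.03 against 122 ± 24.1 CPM, edgeR adjusted p = 0.898) and Ciita (611 ± 39.1 against 721 ± 95.2 CPM, edgeR adjusted p = 0.912) did not pass. Ido1 had 51 counts in the group labelled WT and 0 in the other, without passing (edgeR adjusted p = 0.56). Without Rag2-/- ISG+ DC replicate 2, Cd274 (1.98), Cxcl9 (2.76) and Gbp2 (1.71) lost their calls, and Gbp2 lost it too without Rag2-/- replicate 3, at 1.89, and without WT replicate 2, at 1.52.

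Of 30 macrophage and monocyte markers, 4 rose and none fell over all genes, and 18 rose and 1 fell when adjusted over the list alone (median 1.61, camera adjusted p = 1.38e-23, and adjusted p = 0.06 with an estimated correlation). Arg1 was at 2596 ± 709 CPM against 75.6 ± 21.4. Apoe, a lipid carrier, rose 7.63-fold and the matrix protein Thbs1 5.14-fold; both lost their calls without Rag2-/- ISG+ DC replicate 2, at 2.71 and 2.04. Over all genes, 1 rose without Rag2-/- ISG+ DC replicate 2 and 7 without WT replicate 1, and without CD103+ DC1 replicate 3, 19 rose and 1 fell. None of 38 phagocytic, Fc and pattern receptors passed over all genes, whereas 11 were higher when adjusted over the list alone (median 0.63, camera adjusted p = 2.79e-09, and adjusted p = 0.102 with an estimated correlation). Without Rag2-/- replicate 3, 1 receptor rose, without WT replicate 1, 2 rose, and without CD103+ DC1 replicate 3, 15 rose and 1 fell.

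**Figure D2:**
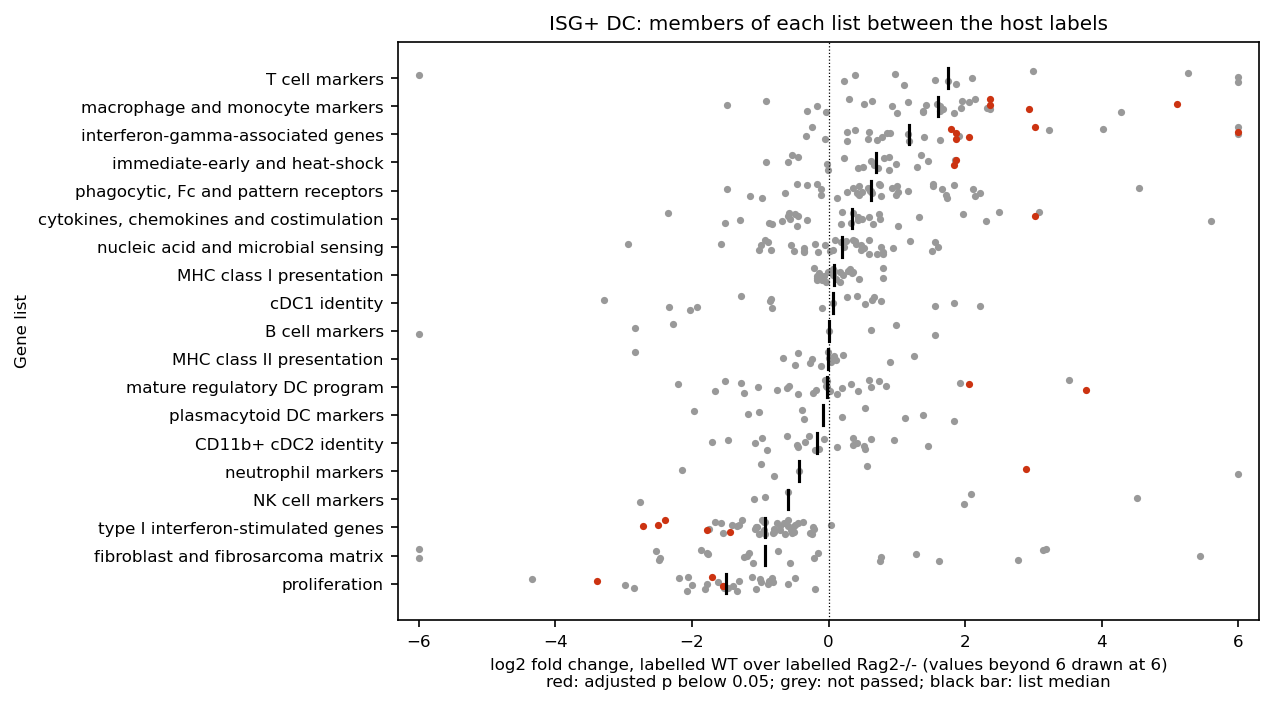
Each point is the log2 fold change of 1 gene between ISG+ DC labelled WT and labelled Rag2-/- (horizontal axis, values beyond 6 drawn at 6) in each of 19 gene lists (vertical axis); red points passed the edgeR test, grey points did not, and black bars are list medians. Medians run from -1.50 for proliferation to 1.75 for T cell markers, with type I interferon-stimulated genes at -0.93 and interferon-gamma-associated genes at 1.18.

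Proliferation genes were lower in all 30 members by sign, with 3 passing over all genes and 17 when adjusted over the list alone (median -1.50, camera adjusted p = 6.13e-21, and adjusted p = 0.0495 with an estimated correlation). Kif20a fell 10.5-fold, Mki67 2.92-fold and Mcm6 3.26-fold. Mki67 and Mcm6 lost their calls without Rag2-/- ISG+ DC replicate 2 (-1.49 and -1.96), without Rag2-/- replicate 3 (-1.60 and -1.40) and without WT replicate 2 (-1.38 and -1.61). Mcm6 lost it also without WT replicate 1, at -1.80. Over all genes, 1 fell without Rag2-/- replicate 2, 2 without Rag2-/- replicate 3, 9 without WT replicate 1, 4 without WT replicate 2 and 13 without CD103+ DC1 replicate 3. Immediate-early and heat-shock genes were higher, with 2 of 22 rising over all genes and 9 rising and 1 falling when adjusted over the list alone (median 0.70, camera adjusted p = 3.93e-08, and adjusted p = 0.156 with an estimated correlation). Over all genes, none rose without Rag2-/- replicate 2, and 10 rose and 2 fell without CD103+ DC1 replicate 3. Fos rose 3.63-fold and Fosb 3.58-fold, and both lost their calls without Rag2-/- replicate 2, at 1.66 and 1.68.

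Population identity lists showed no call, though members passed in some fits. None of 19 DC1 identity genes passed (camera adjusted p = 0.935), with 1 higher and 2 lower when adjusted over the list alone, and none of 22 CD11b+ cDC2 genes passed either way (camera adjusted p = 0.935). Over all genes, 1 DC1 gene rose and 1 fell without Rag2-/- replicate 2, Rag2-/- replicate 3 or WT replicate 1. Without CD103+ DC1 replicate 3, 2 DC1 genes rose and 4 fell, and 2 cDC2 genes rose. MHC class I presentation (23 tested, camera adjusted p = 0.345) and class II presentation (15 tested, camera adjusted p = 0.935) had no member past the test over all genes. Class II had 2 higher and 1 lower when adjusted over the list alone, and the same counts over all genes without CD103+ DC1 replicate 3, with 1 lower without WT replicate 2. H2-K1 was at 1787 ± 34.9 against 1594 ± 69.6 CPM and Ccr7 at 85 ± 22 against 87.2 ± 4.18. The mature regulatory DC list had no call (camera adjusted p = 0.511), though 2 of 29 rose, over all genes and over the list alone: Cd274 and Pdcd1lg2, the PD-1 ligands, the latter 13.7-fold. Pdcd1lg2 lost its call without Rag2-/- ISG+ DC replicate 2, at 3.74, where no gene of the list passed; 5 rose and 4 fell without CD103+ DC1 replicate 3. Il12b was at 10.3 ± 1.6 against 29.6 ± 11 CPM (edgeR adjusted p = 0.295). In the list of cytokines, chemokines and costimulation, Cxcl9 was the 1 gene of 32 to pass, and 2 were higher when adjusted over the list alone. Its median of 0.34 (camera adjusted p = 0.021) had adjusted p = 0.158 with an estimated correlation. That call was also lost without Rag2-/- replicate 2 (0.42), Rag2-/- replicate 3 (0.29), WT replicate 2 (0.05) or CD103+ DC1 replicate 3 (0.26), and with no low-count filter (0.33). The list did not pass fry either (adjusted p = 0.0593). Over all genes none rose without Rag2-/- replicate 2, 2 rose without any other library compared, and 7 rose and 2 fell without CD103+ DC1 replicate 3. Sensing genes had no call (38 tested, camera adjusted p = 0.759), with 2 lower when adjusted over the list alone; 1 rose without Rag2-/- replicate 2, and 3 rose and 4 fell without CD103+ DC1 replicate 3.

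No T cell marker passed between hosts. Il7r was at 141 ± 39.4 against 42 ± 8.78 CPM and Bcl11b at 21.8 ± 12.6 against 2.71 ± 0.992, while Tcf7 had 0 counts in the group labelled WT and 140 in the other (edgeR adjusted p = 0.333, 0.357 and 0.272). Cd3e, chosen after its values were seen, had 4 and 5 counts in the libraries labelled WT and 0 and 0 in those labelled Rag2-/-. Of 13 tested, none passed over all genes or over the list alone, 12 were positive by sign, and the median was 1.75 (camera adjusted p = 0.0158, and adjusted p = 0.158 with an estimated correlation). The list's call was lost without WT ISG+ DC replicate 1, at 1.66. B cell (7 tested), NK cell (7) and plasmacytoid DC (10) lists had no call (camera adjusted p = 0.424, 0.424 and 0.935), with 1 plasmacytoid DC marker lower when adjusted over the list alone. Without CD103+ DC1 replicate 3, 1 T cell and 1 plasmacytoid DC marker rose, 2 NK cell and 1 plasmacytoid DC marker fell, and 2 neutrophil markers rose. On the neutrophil list (7 tested, camera adjusted p = 0.342) Csf3r, the G-CSF receptor, rose 7.46-fold, and 2 were higher and 1 lower when adjusted over the list alone. Csf3r lost its call without Rag2-/- replicate 2, at 3.40, and without replicate 3, at 2.53. Fibroblast and fibrosarcoma matrix genes had a median of -0.93 with none of 24 passing over all genes, and 3 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.00719, and adjusted p = 0.659 with an estimated correlation). That call was lost without Rag2-/- replicate 2 (-0.26), WT replicate 2 (-0.34) or CD103+ DC1 replicate 3 (-0.94), and the list did not pass fry (adjusted p = 0.598). Over all genes, 6 fell without WT replicate 1 (median -2.83), 9 fell with the replicate block (median -2.97), 1 rose without WT replicate 2, and 3 rose and 6 fell without CD103+ DC1 replicate 3. Of the 9 lists called, those for type I interferon-stimulated, interferon-gamma-associated and proliferation genes held with an estimated correlation.

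Among the greatest changes outside these lists, the complement component C3 rose 21.6-fold to 1101 ± 93.7 CPM, Ninj1 23.9-fold and Tnfaip2 14.7-fold. Eif3j, at 0 in the group labelled Rag2-/-, was at least 437-fold higher by its mean, with 44.3 ± 41.5 CPM in the group labelled WT. With an SD close to the mean, the 437-fold does not bound each library. Its call was lost without WT ISG+ DC replicate 2, at a fitted log2 change of 10.53, and without Rag2-/- replicate 2, at 11.95. It was at 12.80 without WT replicate 1. With the group labelled Rag2-/- at 0, these fitted values are not measured sizes. Hist1h2ad (at least 226-fold lower) and Hist1h2ai (-7.05), both replication-dependent histone genes, were among the greatest falls, as were Cyp51 (-4.63) and Brca1 (-3.93). Ninj1 was at 5.54 without Rag2-/- replicate 2, against 4.58. Hist1h2ad, at 0 in the group labelled WT, was at a fitted -10.54, against -11.58, neither of which is a measured size. Without WT replicate 1 and without WT replicate 2, Brca1 was at -5.02 and -3.33. Hist1h2ai was at -6.12 without WT replicate 2. Without WT replicate 1 the WT library left had no counts of Hist1h2ai, so its fitted -12.82 is not a measured size. Cyp51 encodes an enzyme of cholesterol synthesis and was at 3.12 ± 0.11 against 77.6 ± 16.9 CPM.

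**Figure D3:**
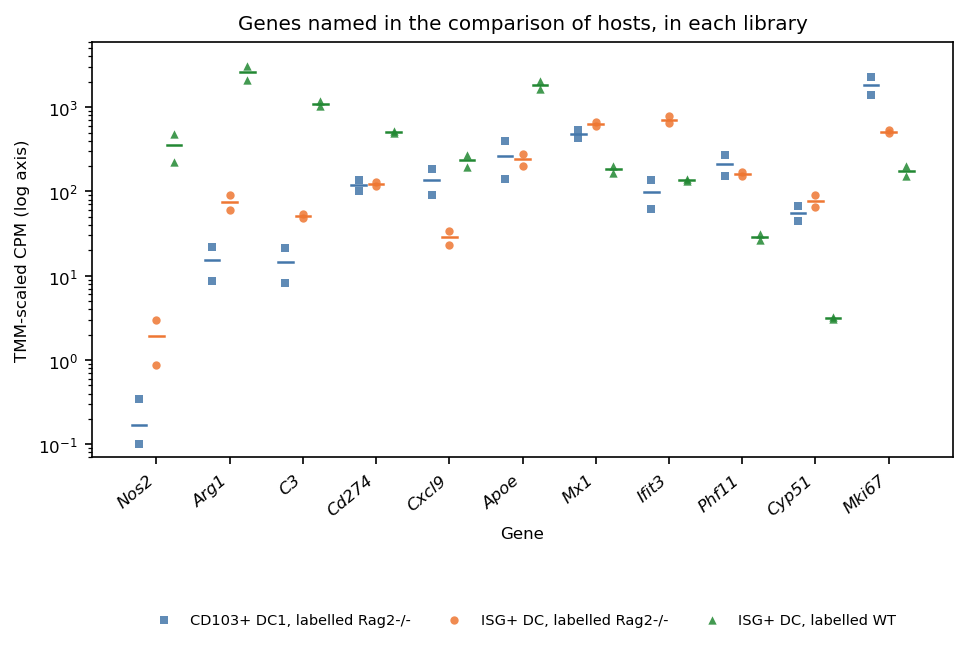
TMM-scaled CPM on a log axis of 11 genes named in the comparison of hosts, in each of the 6 libraries, with points for libraries, short bars for group means, and colors and shapes for the 3 groups; Nos2 at 0 in CD103+ DC1 replicate 2 is drawn at the lower edge. Both ISG+ DC libraries labelled WT lie above both Rag2-/- for Nos2 and Arg1 (group means 353 against 1.94 and 2596 against 75.6 CPM) and below them for Mx1, Ifit3, Phf11, Cyp51 and Mki67.

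For several lists the median, the mean and the test differed in sign, none of them called. Between populations this held for B cell markers (median 0.92, mean -0.31, camera lower). Between hosts it held for DC1 identity (median 0.07, mean -0.24, camera lower), CD11b+ cDC2 identity (median -0.17, camera higher), neutrophil markers (median -0.43, mean 0.92, camera higher) and NK cell markers (median -0.60, mean 0.46, camera lower). It held too for class II presentation, the mature regulatory DC list and plasmacytoid DC markers, with medians of -0.01, -0.02 and -0.08 and a higher direction by camera.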

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

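Leaving CD103+ DC1 replicate 3 out of the comparison of hosts, and removing 4 abundant RNAs, were chosen after seeing the data. Main calls kept by an alternative, 55.9% to 100% between populations and 28.8% to 100% between hosts, kept their direction. Between populations limma-voom kept 73% and the 4 libraries compared alone 57.8%, with 10 and 7 of 57 named genes losing their calls; between hosts 14 of 26 lost theirs without Rag2-/- ISG+ DC replicate 2. Between populations the main count of 488 genes became 1066 by DESeq2, 1087 with no low-count filter, 297 with the 4 libraries compared alone and 1157 with the ISG+ DC of both hosts, and leaving out 1 replicate gave 278 to 2068. It stayed within 1.5 times under 8 other settings, the replicate block among them. Between hosts the main count of 73 became 526 by DESeq2, 476 by limma-voom, 555 with no low-count filter, 47 with a filter of 5 CPM, 444 with the 4 libraries compared alone, 221 at a threshold of 0.1 and 31 against 1.5-fold. Leaving out 1 replicate of the groups compared gave 27 to 198, and leaving CD103+ DC1 replicate 3 out of the shared fit gave 801. Where 1 library is left, it is assumed to vary like the other groups. The causes of these changes were not tested. With an estimated correlation, 2 of 13 lists between populations and 3 of 9 between hosts kept a call. The fibroblast and matrix list turned to higher by camera without WT ISG+ DC replicate 2 (median -0.34, adjusted p = 0.96), with medians of -2.83 to -0.26 over the replicates left out; the cause was not tested. The median of all genes shifted to 0.157 without CD103+ DC1 replicate 2 and to -0.128 without Rag2-/- ISG+ DC replicate 2.

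Whether equal replicate numbers pair the libraries could not be told. Deviations of same-numbered libraries correlated at 0.0162 between populations and -0.0581 between hosts, which share 1 number. With 2 libraries per group the deviations mirror each other, so each pair of groups gives 1 value up to its sign, too little to decide. With the replicate block, 715 genes and 13 lists were called between populations and 258 genes and 10 lists between hosts. Number 1 occurs in WT ISG+ DC alone, so the block absorbs that library and its contrast of hosts rests on WT replicate 2. In simulations with 2 libraries per group, 1.6% and 4.8% of 2-fold changes in genes of at least 10 CPM were recovered. Depth was not varied, and each gene had 1 spread for all groups.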

Other observations

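The tests weighing macrophage share, DC share and scaling were chosen after the results were seen, as were the core macrophage genes and the genes Idi1, Srebf2, Abca1, Vegfa, Ero1l, Flt3, Zbtb46, Dpp4 and Kmo. The 3 tests on genes not looked at before were set before those genes' values were read. From these, Sc5d, Hsd17b7, Tpi1 and Aldoa were picked for naming after their values were seen.

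Some sterol genes were lower in ISG+ DC labelled WT. Cyp51, Idi1 (-3.29) and Srebf2 (-1.96), the last a regulator of cholesterol synthesis, fell by edgeR's quasi-likelihood test, while 8 of the 12 sterol genes seen first did not pass, all 12 being negative by sign. A candidate explanation is lower sterol synthesis as a program, tested on members of the pathway not looked at before. Of 11 tested, 9 were negative by sign and none passed alone (median -1.43, camera adjusted p = 0.000135 over 3 lists, and adjusted p = 0.0738 with an estimated correlation). Sc5d was at 1.01 against 24.8 CPM and Hsd17b7 at 1.16 against 20.6 CPM.

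Of the targets of the liver X receptor, which responds to sterols, the cholesterol exporter Abca1 rose 14-fold and Apoe 7.63-fold, and 6 of 9 targets not looked at before were positive by sign, with none passing alone (median 1.09, camera adjusted p = 0.000134, and adjusted p = 0.0738 with an estimated correlation). Of 12 hypoxia and glycolysis genes seen first, 11 were positive by sign and 2 passed, Vegfa (9.97-fold) and Ero1l (5.97-fold). Of 25 further hypoxia and glycolysis genes, 23 were positive by sign and none passed alone (median 1.09, camera adjusted p = 1.43e-10, and adjusted p = 0.0754 with an estimated correlation), with Tpi1 at 265 against 101 CPM and Aldoa at 1003 against 441 CPM. Lower sterol synthesis, liver X receptor activity and a hypoxic or glycolytic state of the WT-labelled cells may each underlie these shifts, and a different mix of sorted cells was not tested for them.

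All 10 core macrophage genes were positive by sign in ISG+ DC labelled WT, with none passing (median 1.51), and 4 conventional DC genes, Flt3, Zbtb46, Dpp4 and Kmo, were negative, of which Flt3 passed the edgeR test (median -1.39). The lists fixed beforehand for DC1 and CD11b+ cDC2 identity had medians of 0.07 and -0.17. A larger share of the macrophages already in the Rag2-/- sort may account for the macrophage part, and would raise their genes by one factor. Arg1 exceeded the core median by 3.59 ± 0.484 on the log2 scale, where the spread joins the SE of Arg1 with a bootstrap over the core genes. Yet core genes were at 123 CPM (median) in the Rag2-/- sort, so they can hide a greater factor if the DC express them. More macrophages, Arg1-rich macrophages and a changed state of the sorted cells between hosts cannot be told apart, since no sort gate or purity is given.

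Type I interferon-stimulated genes were lower while interferon-gamma-associated genes were higher in the same libraries. A scaling error would shift both lists alike, and their medians lay 2.11 ± 0.376 apart, which argues against it. For these differences of medians, ± is a standard error from 2000 bootstraps over the genes of each list. It takes genes as independent and does not measure the spread between libraries. The interferon-gamma median lay -0.328 ± 0.394 from that of core macrophage genes, and the type I median 0.469 ± 0.385 from that of the conventional DC genes. A larger macrophage share could account for the median of the interferon-gamma list. In that list Nos2 (7.52 ± 0.76 SE) and Cxcl9 (3.02 ± 0.42 SE) exceeded the core median of 1.51, while 3 of the 27 members were negative by sign. The limit given for Arg1 holds for these genes too. A smaller DC share as the cause of the type I part rests on 4 genes chosen after seeing. The fixed cDC2 list, some of whose genes macrophages share, had a median of -0.17. Neither share is told apart from a lymphocyte effect, which the labels' host difference leaves open and untested.

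ISG+ DC labelled WT were also set against CD103+ DC1 labelled Rag2-/-, where host and population differ together. Type I interferon-stimulated genes had a median log2 difference of 0.05 over members going both ways, 7 higher and 5 lower by edgeR (camera adjusted p = 0.733), interferon-gamma-associated genes 1.97 (camera adjusted p = 3.29e-16, and adjusted p = 0.0271 with an estimated correlation) and proliferation genes -2.59 (camera adjusted p = 1.75e-25, and adjusted p = 0.0271 with an estimated correlation).

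Xist was at 1218 to 1724 CPM in all 6 libraries. Kdm5d and Uty were at 0 in all 6, Ddx3y had 2.14 and 1 estimated counts in the libraries labelled WT, and Eif2s3y had 11 in Rag2-/- ISG+ DC replicate 3. Of the erythroid genes, Hba-a1 ran from 0 CPM in CD103+ DC1 replicate 3 to 46.7 CPM in Rag2-/- ISG+ DC replicate 3, and none of the 4 tested passed in either comparison, though 1 erythroid gene rose between populations without CD103+ DC1 replicate 2.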
